A study of Mus musculus with 8 samples.

How the data were processed

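Polyadenylated RNA from whole liver of male mice was sequenced from 8 Illumina TruSeq libraries, per the labels' protocols, 4 from mice given IgG and 4 from mice given antibody against CD47. The deposited count table holds estimated counts per Ensembl gene, whole numbers in every cell, with no normalization. Per the submitters' processing notes, Salmon 1.3.0, DESeq2 1.32.0 and the mouse build GRCm39 were used, with no role stated for each; whether the whole numbers are rounded Salmon estimates is not given in the sources used here. The authors' deposited comparison table holds a mean normalized count (a signal averaged over libraries), a log2 fold change with its standard error, a p-value and adjusted p-value, and a rank score per gene, per the file headers. The log2 fold divided by its standard error gave the listed p-value within 1.5 times for 6589 genes only, so the deposited log2 folds may be shrunken, and the table was used only for its signs, p-values and adjusted p-values. The reference group of that table is not stated in the sources used here.

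Counts of 54309 genes were read, of which 27899 had no count in any library. Symbols came from a reference annotation for 51484 genes and from the authors' deposited table for 17 more. The reference annotation is of an older mouse build than GRCm39, so it was used for names and for transcript length and GC content only, and no coordinates are given. Columns were matched to samples by their titles, and 0 columns of values were left unused. The smallest chi-square per degree of freedom between 2 libraries of a group was 26.989, where sampling noise alone gives about 1. The labels describe separate mice for the treatments but do not link a library to an animal; if libraries shared animals, p-values would measure technical spread only. The IgG and antiCD47 libraries share the numbers 1 to 4, and nothing in the labels says that a number marks a pair.

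Genes were filtered with filterByExpr by group and scaled with TMM in edgeR 4.0.16 (R 4.3.3), and the treatments were compared with glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the 15472 genes tested. The common dispersion was 0.028, a biological coefficient of variation of 16.7%. CPM is the usual count share of the TMM-scaled library size. Total counts of 43691472 to 55477484 per library set the counting precision, and intervals on counts (95%, exact binomial) cover counting error only.

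Before the data were examined, 35 gene lists (7 of them primary), the rule for named genes, the test and most alternatives were fixed. The rule names Cd47, Sirpa, Mertk, Ripk3, Mlkl, Col1a1, Acta2, Timp1 and Spp1 whatever their result, the 12 higher and 12 lower genes with the smallest p past the threshold, leaving out predicted gene models, up to 4 members of each list with the smallest p, and any list member that passes adjusted over the list alone. Some further members past the threshold are named under that last part, and single results of some genes are not reported here. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 35 lists, with an estimated correlation and with fry as alternatives. Of the list members, 2 matched no gene in the count table. The list score of a library is the mean over members of its log2 CPM (prior count 2) minus the IgG mean. Single measures were compared by an exact permutation test in scipy 1.17.1.

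The tests were checked on simulated data drawn from these libraries' means and sizes for antiCD47 against IgG. With 15257 genes in the step, edgeR recovered 47.8% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 100% of those changed 4-fold, with 3.8% of calls false. limma voom recovered 44.8%, 77.6% and 100% with 3.3% false. DESeq2 1.42.0 recovered 67.2%, 94% and 100% over 15472 genes with 16.3% false. These shares come from a single draw with dispersions estimated by edgeR, in which 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold. More genes were called in the data, so the false shares need not carry over to them. Of 100 random unchanged lists, camera called 0 and fry 4 at p under 0.05; those simulated genes vary independently, so the check does not cover correlated genes.

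Alternatives were DESeq2 size factors, library totals and upper quartile scaling in edgeR, no low count filter, a minimum of 10 counts in every library of a group, DESeq2, limma voom with and without quality weights, the robust quasi-likelihood fit, the replicate number as a block, leaving out each library in turn, an adjusted p of 0.1 and a 2-fold minimum. Leaving out IgG 2 and antiCD47 2 together was added after seeing the data, as were 9 further gene lists (platelets, erythroid precursors, vascular smooth muscle, periportal and pericentral hepatocytes, motile cilia, nucleolar ribosome biogenesis, ribosomal proteins and mitochondrially encoded mRNAs). Figures were drawn with matplotlib 3.10.9.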

Results

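Liver RNA was sequenced from male C57BL/6 mice kept for 16 weeks on a diet rich in fructose, palmitate and cholesterol, which produces steatohepatitis, an inflamed and scarred fatty liver. From week 8 to week 16 the mice were injected with a control antibody (IgG) or with an antibody against CD47 (200 µg per mouse), the surface protein that binds SIRPα on macrophages and restrains engulfment. The series describes 7 to 8 mice per treatment, and 4 libraries of each treatment were measured here, named IgG 1 to 4 and antiCD47 1 to 4. Total counts lay between 43691472 and 55477484 per library. No pair of libraries agreed within sampling noise, so all 8 entered as separate samples. The comparison asks, per the series title, how blocking CD47 changes the clearance of necroptotic hepatocytes by macrophages and the scarring of the liver.

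In the antiCD47 livers 18 of 34 genes of stellate cell activation and fibrillar matrix and 12 of 15 biliary and progenitor markers fell, and 17 of 25 acute phase genes, 11 of 11 measured neutrophil, 8 of 14 measured erythroid and 10 of 18 Kupffer cell markers rose. As sets, none of these 6 lists passed with an estimated correlation between genes (camera adjusted p = 0.249 to 0.308). By fry, all 6 passed (adjusted p = 0.0163 to 0.0472). That set test asks whether members change at all, not whether they change more than other genes as camera does. Of 15472 genes tested, 1678 passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, two-sided), with 842 higher and 836 lower in antiCD47. At least 2-fold changes were seen in 502 of them, 178 higher and 324 lower. The 4 libraries of each treatment did not overlap in 3034 tested genes (19.6%, against 2.9% by chance), among them 1525 of the genes past the threshold. Scaling by library totals alone gave 428 higher and 3153 lower genes and moved the median of all genes to -0.19 on the log2 scale, and upper quartile scaling gave 634 higher and 969 lower. The number of genes past the threshold depended on single libraries: it was 174 without IgG 1, 92 without IgG 3, 2 without IgG 4, 3630 without antiCD47 1, 756 without antiCD47 2 and 21 without antiCD47 3. In each of these fits all 1678 genes kept their direction and an unadjusted p under 0.05. These genes were chosen with all libraries and each fit reuses most of them, so that is not independent support.

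Among the genes with the smallest p, Hacl1, which encodes a peroxisomal lyase of fatty acid alpha-oxidation, rose by a log2 fold change of 1.11 ± 0.09 (SE; edgeR adjusted p = 0.00437), from 88.8 ± 10.2 to 192 ± 11.9 CPM (count share of the TMM-scaled library size; mean ± SD, n = 4 per treatment). Cobl (log2 0.77), Tacc1 (0.85), Atxn1 (0.82), Ifitm1 (1.06) and Cpne8 (1.79) also rose, as did Wdr75 (0.62), a nucleolar protein gene. F13a1, which encodes the A chain of coagulation factor XIII, rose by 2.32 ± 0.29. The remaining 4 of the 12 higher genes with the smallest p were red cell genes, described with their list. Of the 12 lower genes, Atp1b1, a sodium pump subunit, changed by -0.92 ± 0.10 (edgeR adjusted p = 0.0113), and the matrix-associated genes Smoc2 (-1.13), Mgp (-1.24) and Adamts2 (-0.96), a procollagen protease, fell with it. Plekha7 (-0.91), Sh2d4a (-1.35), Spry1 (-0.77), Tns1 (-0.67) and Olfm3 (-0.93) were lower as well. Gabrp had 73 counts over the IgG libraries and 6 over the antiCD47 libraries, a ratio of 0.0914 with a 95% counting interval of 0.0325 to 0.209. Lox and Col1a2, the last of the 12, belong to the matrix list.

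**Figure D1:**
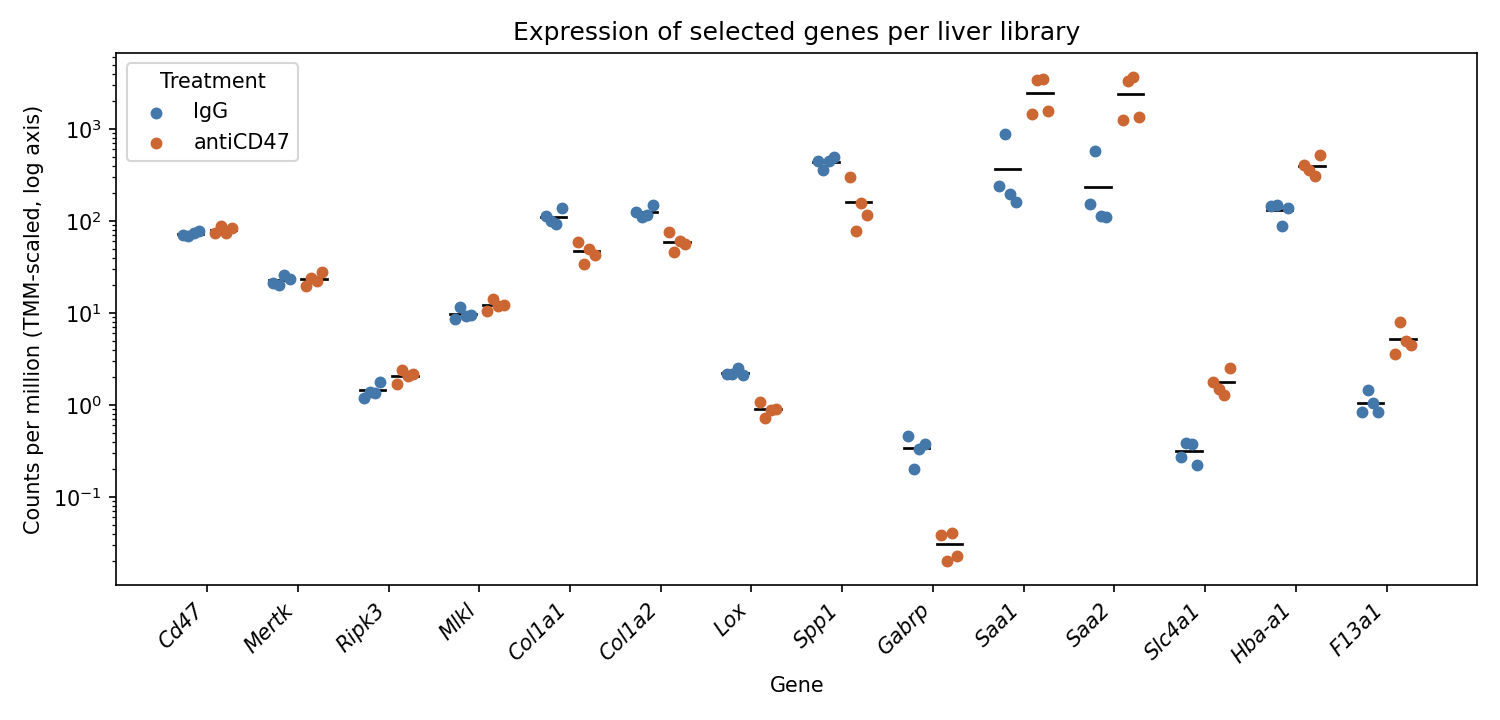
Expression of 14 named genes in each liver library, in CPM on a log axis. Points are single libraries (4 IgG, 4 antiCD47) and bars are group means; Cd47 and Mertk overlap between treatments, while Col1a1 went from a mean of 111 to 46.7 and Hba-a1 from 131 to 401 CPM.

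Cd47 itself, the antibody's target, had a log2 fold change of 0.14 ± 0.08 (SE; edgeR adjusted p = 0.24), with 72.8 ± 4.18 CPM in IgG and 80.3 ± 7.34 CPM in antiCD47. Its receptor gene Sirpa was at 60.7 ± 11.5 and 60.6 ± 6.69 CPM (edgeR adjusted p = 0.993), and Mertk, an engulfment receptor, was at 22.6 ± 2.45 and 23.4 ± 3.46 CPM (edgeR adjusted p = 0.815). None of these 3 differed beyond the spread between libraries.

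Of the 34 members of the list of stellate cell activation and fibrillar matrix, 18 fell, 1 rose and 15 did not pass, and adjusted over the list alone 21 fell and 2 rose. Col1a1, the main chain of type I collagen, changed by -1.25 ± 0.17 on the log2 scale (edgeR adjusted p = 0.0147), from 111 ± 19.98 to 46.7 ± 10.7 CPM. Col1a2 (-1.08), Col3a1 (-1.18), the collagen crosslinking enzyme gene Lox (-1.32) and the gelatinase gene Mmp2 (-1.62) fell too. Fn1, which hepatocytes also express in quantity, was the member that rose (0.74). Acta2, the smooth muscle actin of activated stellate cells, was at -0.33 ± 0.32 (edgeR adjusted p = 0.502) and Timp1 at 0.35 ± 0.31 (edgeR adjusted p = 0.448); neither passed. By limma voom with quality weights Acta2 was at -0.89 (adjusted p = 0.0446; 0.0446 to 0.823 over the alternatives). The list median was -0.66 (camera adjusted p = 9.51e-12; adjusted p = 0.308 with an estimated correlation; fry adjusted p = 0.0217). Of 18 markers of quiescent stellate cells and portal fibroblasts, 4 fell, among them Eln (-1.92) and Dpt (-1.46), and 3 rose, among them Hhip (1.96) and Ngfr (1.18), with no change of the list (camera adjusted p = 0.265).

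Biliary and progenitor markers fell in 12 of 15 measured members, with none higher. Epcam (-1.62), Tspan8 (-1.59), Prom1 (-1.41) and Bicc1 (-0.98), epithelial genes of bile ducts, were among them, and so was Spp1, the osteopontin gene, which went from 439 ± 58.1 to 163 ± 97.4 CPM (log2 -1.43 ± 0.35, edgeR adjusted p = 0.0338). All 15 were lower adjusted over the list alone. Its members had a median of -1.16 (camera adjusted p = 2.16e-13; adjusted p = 0.249 with an estimated correlation; fry adjusted p = 0.0163). Of 26 cell cycle genes, 3 fell: Rrm2 (-1.07), Top2a (-0.76) and Ccnd1 (-0.65). None rose, and the list median was -0.63 (camera adjusted p = 3.48e-07; adjusted p = 0.515 with an estimated correlation; fry adjusted p = 0.0789). The cell cycle score of antiCD47 1 was -0.04, level with the lowest IgG score, while the 3 other antiCD47 libraries lay lower.

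Acute phase genes, which hepatocytes switch on in inflammation, rose in 17 of 25 members and fell in none (21 rose adjusted over the list alone). Saa2 (log2 3.35 ± 0.63), Saa1 (2.75 ± 0.58), Steap4 (2.65), Serpina3n (1.84), Orm2 (1.83) and Lbp (1.76) rose. Saa3 rose by 4.26 ± 0.90, from 8.14 ± 2.23 to 155 ± 196 CPM, with 445 CPM in antiCD47 2 and 14.6 to 106 in the others. Without antiCD47 2 the Saa3 value was 2.86, and without IgG 2 Saa1 was at 3.65 and Saa2 at 4.27. Saa1, Saa2 and Saa3 did not pass without IgG 1, IgG 3, IgG 4 or antiCD47 3 (adjusted p = 0.0637 to 0.0825). The list took 2.08 ± 0.68% of counts in IgG and 4.62 ± 1.33% in antiCD47 (SD, n = 4 each; exact permutation p = 0.0286, two-sided, the smallest this design can give). IgG 2 had the highest score among the IgG libraries, 0.89 above the IgG mean, and antiCD47 1 the lowest among the antiCD47 libraries, at 1.14. The list median was 1.44 (camera adjusted p = 4.1e-18; adjusted p = 0.308 with an estimated correlation; fry adjusted p = 0.0472).

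**Figure D2:**
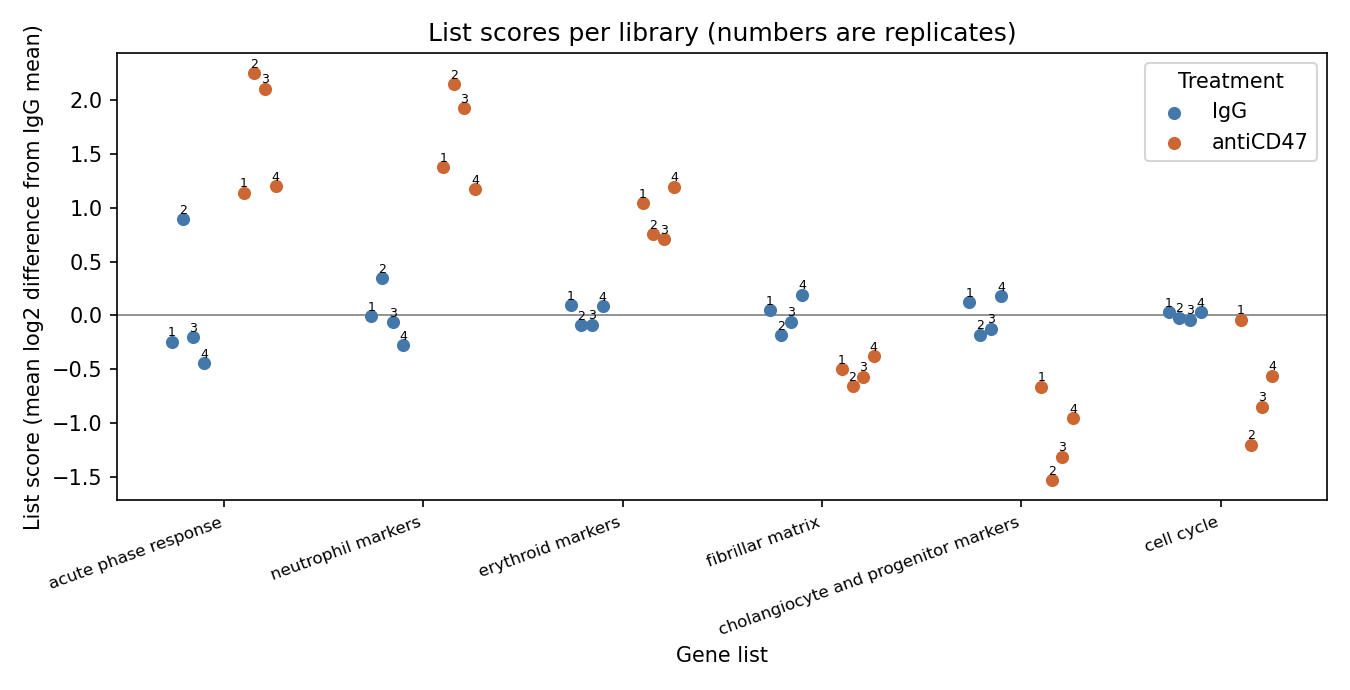
Scores of 6 gene lists in each library, as the mean log2 difference from the IgG mean over the list's members. Points are single libraries with their replicate number; the acute phase score of IgG 2 (0.89) lies close to that of antiCD47 1 (1.14), and the cell cycle score of antiCD47 1 (-0.04) lies with the IgG libraries.

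Of 16 neutrophil markers 11 were measured, and these 11 rose, among them the calprotectin genes S100a8 (2.34) and S100a9 (2.27), the lectin gene Clec4d (1.81) and the chemokine receptor gene Cxcr2 (1.48). Csf3r and Il1r2 did not pass in the authors' deposited table (DESeq2 adjusted p = 0.113 and 0.107). Lcn2 is a member of the acute phase list too. The members' median was 1.81 (camera adjusted p = 1.68e-11; adjusted p = 0.249 with an estimated correlation; fry adjusted p = 0.0163). Of 18 erythroid markers 14 were measured, and 8 rose. Slc4a1, the band 3 anion exchanger of red cells, rose by 2.48 ± 0.29 (edgeR adjusted p = 0.0129), and the globin genes Hba-a1 (1.61), Hbb-bs (1.57) and Hba-a2 (1.53) rose with it. Globin copies are near-identical, so the split of reads between Hba-a1 and Hba-a2 is uncertain. Alas2 (0.45), the first enzyme of heme synthesis in red cells, was also higher. The list median was 0.99 (camera adjusted p = 4.2e-09; adjusted p = 0.249 with an estimated correlation; fry adjusted p = 0.0163).

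Kupffer cell markers rose in 10 of 18 members and fell in none, and 13 rose adjusted over the list alone. Fcna (1.39 ± 0.22), Folr2 (1.18 ± 0.22), Clec4f (1.09 ± 0.23) and the hemoglobin scavenger receptor gene Cd163 (2.33 ± 0.50) had the smallest p. Marco (3.60 ± 0.92) and Timd4 (2.16 ± 0.59) rose with a wider spread: Marco was at 2.88 without antiCD47 2 and at 4.62 without IgG 3, and Timd4 at 2.96 without IgG 3. Neither passed without IgG 1, IgG 2, IgG 3, IgG 4, antiCD47 2 or antiCD47 3 (adjusted p = 0.0596 to 0.0989 for Marco and 0.0508 to 0.116 for Timd4). The median over members was 0.65 (camera adjusted p = 3.3e-10; adjusted p = 0.308 with an estimated correlation; fry adjusted p = 0.0342). Markers of recruited and lipid-associated macrophages did not change as a list (camera adjusted p = 0.656): 1 of 24 rose (Itgam, 0.90), 2 fell (Cd63, -0.77, and Spp1), and Lpl was at 0.54 (edgeR adjusted p = 0.0537; 0.0208 without antiCD47 1).

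Heme and iron genes rose in 7 of 23 members. Hmox1, which breaks down heme, rose by 1.64 ± 0.31, the iron transporter gene Slc11a2 by 1.15, Spic, a transcription factor of heme-handling macrophages, by 1.57, and Hamp, the hepcidin gene, by 1.14. The list median was 0.16, and -0.02 when libraries were scaled by their totals alone (camera adjusted p = 0.000595; adjusted p = 0.308 with an estimated correlation; fry adjusted p = 0.0342).

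Of 29 efferocytosis genes, 4 rose and 2 fell, and the list did not pass (camera adjusted p = 0.21; 0.0445 without IgG 3). The scavenger receptor gene Msr1 (1.29 ± 0.18), the integrin gene Itgb3 (0.91 ± 0.21), Abca1 (0.87) and Timd4 rose. Mfge8 (-0.94 ± 0.15), which bridges dying cells to integrins, and another integrin gene, Itgb5 (-0.54 ± 0.14), fell. Adjusted over the list alone, 7 rose and 3 fell.

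Of 18 necroptosis genes, 4 rose: the death receptor gene Fas (1.29 ± 0.24), Tnfrsf1a (0.74 ± 0.18), Ripk1 (0.52 ± 0.12) and Casp8 (0.49 ± 0.10), a protease that cleaves RIPK1 and restrains necroptosis. Ripk3 was at 0.52 ± 0.18 (edgeR adjusted p = 0.0889 over all genes) and passed only adjusted over the list alone, where 7 members were higher. Mlkl, the pore-forming effector, was at 0.32 ± 0.12 (edgeR adjusted p = 0.105). Over the alternatives the adjusted p ran from 0.0296 to 0.258 for Ripk3 and from 0.0329 to 0.417 for Mlkl, and both passed by voom with quality weights and without antiCD47 1 (0.0441 and 0.045). The median of the list was 0.29, and 0.09 with scaling by library totals (camera adjusted p = 0.000757; adjusted p = 0.477 with an estimated correlation; fry adjusted p = 0.0763). Of 26 inflammatory cytokines and chemokines, Cxcl13 (4.99 ± 0.74), Ccl24 (1.18 ± 0.29) and Il1b (0.78 ± 0.21) rose. The call of Il1b (edgeR adjusted p = 0.0438) was lost in 11 of 19 alternatives. Icam1 was at 1.08 (edgeR adjusted p = 0.0585, and 0.012 without antiCD47 1). Cxcl13 went from 0.103 ± 0.0254 to 3.33 ± 2.98 CPM, and its log2 fold change was 4.20 without antiCD47 2, with an adjusted p of 0.0508 without IgG 3, 0.0583 without IgG 4 and 0.0572 without antiCD47 3. The list score of antiCD47 1 was -0.17, within the IgG range of -0.22 to 0.15. The median member was at 0.24, and at 0.05 with scaling by library totals (camera adjusted p = 0.00994; adjusted p = 0.607 with an estimated correlation; fry adjusted p = 0.219; 0.0647 by camera without IgG 2 and antiCD47 2, left out after the data were seen).

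**Figure D3:**
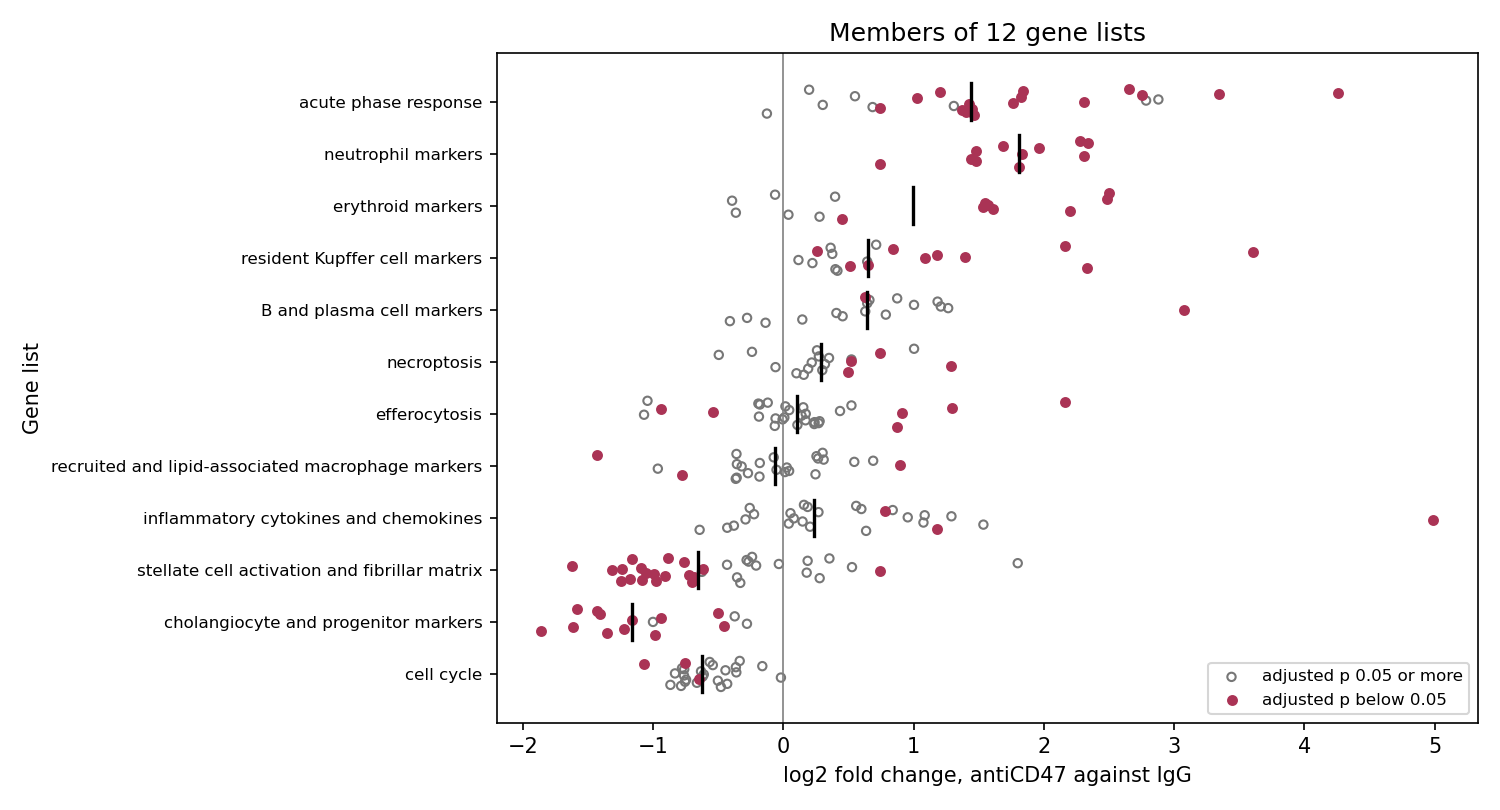
Log2 fold changes of antiCD47 against IgG for the measured members of 12 gene lists, 1 point per gene. Filled points passed an edgeR adjusted p of 0.05 and black bars are list medians, which run from -1.16 for biliary markers to 1.81 for neutrophil markers.

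Among other lists, 4 of 20 stress response genes rose: Dnajb9 (1.04), Xbp1 (0.63), Atf4 (0.52) and Ppp1r15a (0.37). Ppp1r15a (edgeR adjusted p = 0.0459) was lost in 12 of 19 alternatives and did not pass in the authors' deposited table (DESeq2 adjusted p = 0.479). The stress response list had a camera adjusted p of 0.000197, and of 0.495 with an estimated correlation. Of 29 interferon response genes, Gbp5 (1.93), Cd274 (1.41) and Mx2 (0.88) rose (camera adjusted p = 0.000198; adjusted p = 0.607 with an estimated correlation). Of 17 B and plasma cell genes, Ighg2b (3.08) and Xbp1 rose, and Ighm was at 1.21 (edgeR adjusted p = 0.0509). Xbp1 is a member of the stress response list too, so its rise is not particular to these cells. It was at 145 to 301 CPM over the libraries, while Ighg2b was at 0.218 to 5.90 CPM. The B and plasma cell list had a camera adjusted p of 0.00215, of 0.308 with an estimated correlation, and a fry adjusted p of 0.0342. The cytochrome P450 genes Cyp2c29 (1.67), Cyp2c54 (1.68), Cyp2c37 (1.28) and Cyp2c50 (0.77), close copies of each other whose reads may be split uncertainly, were the 4 of 23 drug metabolism genes that rose, with Cyp2c54 at 1.05 without antiCD47 2 and not past without IgG 1, IgG 2, IgG 3, IgG 4 or antiCD47 3 (adjusted p = 0.0625 to 0.104; list camera adjusted p = 0.0112; 0.0615 without IgG 4; adjusted p = 0.477 with an estimated correlation). Of 25 hepatocyte identity genes 3 rose, among them Hnf4a (0.58) and Fgb (1.37). Fgb is a member of the acute phase list too. The hepatocyte identity list had a camera adjusted p of 0.00889, and of 0.607 with an estimated correlation. Its median of 0.12 became -0.07 under scaling by library totals. Of 21 sex-biased and growth hormone dependent genes, 1 rose, and 0 adjusted over the list alone (camera adjusted p = 0.0179; adjusted p = 0.449 with an estimated correlation). That call was lost in 6 of 21 alternatives, among them without IgG 2 (0.0678), without antiCD47 1 (0.136), with quality weights (0.144) and by fry (0.0763). In 5 of these lists 1 antiCD47 library scored within the IgG range: antiCD47 1 for interferon (-0.06; IgG -0.23 to 0.24), stress response (0.08; -0.06 to 0.17) and drug metabolism (0.17; -0.19 to 0.26), antiCD47 4 for hepatocyte identity (0.05; -0.12 to 0.10) and antiCD47 3 for sex-biased genes (0.27; -0.25 to 0.52).

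Lists of lipid, bile acid and amino acid metabolism did not pass by camera with all libraries, and each passed in some of 21 alternatives: cholesterol synthesis in 8, lower (7.61e-05 without antiCD47 1, 0.0429 without IgG 2, 0.0445 without IgG 3), bile acids in 4, higher (0.0184 without IgG 1), fatty acid synthesis in 4, lower (0.0128 without antiCD47 1, 0.0312 without IgG 3), gluconeogenesis in 4, lower (0.0475 without IgG 4, 0.0295 without antiCD47 2), and fatty acid oxidation in 2, higher (0.0476 without IgG 2). Gpam (-0.56), Srebf1 (-0.34) and Mid1ip1 (-0.60) fell among 26 genes of fatty acid and triglyceride synthesis (adjusted p = 0.11), and of 25 genes of fatty acid oxidation 3 rose, among them Acot1 (0.60) and Ehhadh (0.32), and 1 fell (adjusted p = 0.306). Of 19 genes of bile acid synthesis and transport 3 rose, among them Cyp2c70 (0.91) and Baat (0.32), and the sterol exporter gene Abcg8 (-0.41) fell (adjusted p = 0.0908). Ppargc1a (-0.99), Agxt (-0.54) and Hal (-0.43) fell among 21 of gluconeogenesis and amino acid catabolism (adjusted p = 0.149). None of 24 cholesterol synthesis genes passed (adjusted p = 0.0855). The camera adjusted p was 0.881 for phagolysosome genes, 0.541 for T and NK cells (0.0363, lower, without IgG 3), 0.342 for dendritic cells, 0.645 for endothelium, 0.263 for MHC class II (0.0348, lower, without IgG 1), 0.823 for p53 targets, 0.533 for oxidative phosphorylation (0.0111, lower, with scaling by library totals), 0.819 for immediate early genes, 0.572 for pancreas, where 1 of 14 members was measured, and 0.348 for adipose and mesothelium, where 7 of 12 were. The clock list did not pass either (0.599), with 3 members higher, among them Cry1 (0.68), and 5 lower, among them Dbp (-0.94), Hlf (-0.59) and Per3 (-0.61).

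In all, 16 of the 35 lists passed by camera with its preset correlation, 13 higher and 3 lower, 8 passed by fry, and 0 passed by camera with an estimated correlation (5 at an unadjusted p under 0.05). Regrouping the 8 libraries without regard to treatment gave as many lists by the preset camera test in 14 of 35 arrangements, the real one included, so that number does not set the treatments apart. The count of single genes does: the highest of the other arrangements gave 5.

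The first principal component of log2 CPM held 47.7% of the variance. IgG libraries lay between -36.3 and -17.6 on it, antiCD47 1 at 0.9, antiCD47 4 at 20.1, antiCD47 3 at 36.4 and antiCD47 2 at 62.3. Pearson correlations across genes were 0.986 to 0.988 within IgG, 0.975 to 0.986 within antiCD47 and 0.960 to 0.986 between treatments, where genes are not independent replicates. Mitochondrially encoded genes took 6.34 ± 0.28% of counts in IgG and 7.49 ± 0.45% in antiCD47 (SD, n = 4 each; exact permutation p = 0.0286, two-sided), and albumin 4.53 ± 0.27% and 4.36 ± 0.23% (exact permutation p = 0.4).

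The authors' deposited table listed 2648 distinct genes past an adjusted p of 0.05, 1399 with a positive and 1249 with a negative fold change. Of the 1678 genes called here, 1622 were in the authors' deposited table, 1511 of them past its threshold, and 0 of these 1511 had the opposite sign. DESeq2 run here on the counts called 3145 genes, of which 2393 were among those of the authors' deposited table.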

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

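The tests of globin copies, whole blood, erythroid precursors, dilution, non-hepatocyte RNA, portal tracts, an ill animal and time of day were chosen after related results had been seen; the test of length and GC content and the regroupings of libraries were set before theirs were. A demand that 80% of a list be measured was added after the platelet and precursor medians were seen. Without it, whole blood and erythroid precursors would both have been argued against by the rules set for them. Of the lists fixed before, neutrophil (11 of 16), erythroid (14 of 18), adipose and mesothelial (7 of 12) and pancreas markers (1 of 14) fall short of the 80% demand too. The acute phase test was moved from a camera p to library scores after the regroupings were seen. Intervals of list medians, here and below, came from a bootstrap over a list's genes, not over mice. They hold no spread between animals and treat correlated genes as independent.

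Of 308 groups of 4 libraries checked for a library far from the other 3, 21 held one, where chance gives about 15.4, and 12 of the 21 concerned IgG 2. In IgG 2 these 6 acute phase genes lay above the other IgG libraries: Saa1 at 881 CPM (others 160 to 238), Saa2 at 572 (109 to 153), Steap4 at 700 (225 to 244), Serpina3n at 806 (324 to 398), Orm2 at 113 (up to 56.5) and Fgb at 3890 (2090 to 2170). Hamp at 245 CPM, Fas at 24.5, Atf4 at 57.6 and the stress response score at 0.166 were also highest there, and Spry1 at 7.77 CPM and Mid1ip1 at 27.7 lowest. In antiCD47 2, Cyp2c50 at 686 CPM (others 417 to 431), Cyp2c54 at 161 (42.5 to 54.3), Cyp2c37 at 379 (122 to 144) and Spic at 7.65 (2.52 to 3.03) stood above the rest, and so did the clock score at 0.088. Hba-a1 in IgG 3 was at 89.1 CPM (others 139 to 149). Per3 in IgG 4 was at 27.2 CPM (21.7 to 22.3), the bile acid score of IgG 1 at 0.169, and the endothelial score of antiCD47 4 at 0.11. These flags are correlated, since acute phase genes move together.

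The real grouping gave 1678 genes past the threshold, and 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many; the highest of the others gave 5. That share, the smallest 35 splits can give, argues against chance for the count of genes, although 2 genes passed without IgG 4. For gene lists chance is not argued against: 14 of 35 splits gave at least the 16 lists of the real grouping by camera with its preset correlation, and the highest of the others gave 21. Other splits gave a median of 15 lists, and 6 at the lowest. The lists' members are correlated within livers, and the preset correlation does not allow for that. Ranking each list by the size of its median log2 fold change, a test chosen after this was seen, put the real grouping first of 35 for 9 lists, where 1 is expected: acute phase, neutrophil, erythroid, biliary, matrix, B and plasma cell, cell cycle, drug metabolism, and adipose and mesothelial markers. All lists were ranked on the same splits of the same libraries and some share members, so these 9 are not separate results. The next split came close for B and plasma cells (0.614 against 0.644), cell cycle (0.591 against 0.625) and adipose and mesothelial markers (0.718 against 0.787). For Kupffer cells and for necroptosis 2 of 35 splits were as large, for heme and iron 4, and for inflammatory cytokines and chemokines 13.

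Matrix and biliary transcripts were lower in antiCD47. Dilution by acute phase transcripts is argued against, since the added share of raw counts can lower other genes by -0.038 on the log2 scale only. Under scaling by library totals, which leaves such dilution in, the list medians were -0.842 and -1.333. With TMM, which allows for it, they were -0.66 and -1.16. That covers dilution by the acute phase list only. A general loss of non-hepatocyte RNA is argued against by endothelial scores that exceeded matrix scores by at least 0.409 in each antiCD47 library (at most 0.137 in IgG), and length and GC content by a matrix median of -0.558 and a biliary median of -1.11 after their trend was removed. Fewer portal tracts in the pieces sampled cannot be told apart from a treatment effect: vascular smooth muscle markers had a median of -0.247 (bootstrap interval -0.378 to -0.013) and periportal hepatocyte genes -0.135 (-0.269 to 0.033). A lower content of matrix-producing and biliary cells under CD47 blockade stays an untested biological explanation beside it.

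Erythroid transcripts were higher in antiCD47. Reads shared between globin copies are argued against, since 4 erythroid genes outside the globin family, among them Slc4a1, Trim10 and Alas2, passed the threshold, more than chance gives. More whole blood in the tissue pieces cannot be told apart: platelet markers had a median of 0.887 (0.221 to 1.21) below the globin median of 1.56, but 7 of 16 were measured, and they went both ways: Pf4 was at -0.24 ± 0.20 and Itga2b at 0.22 ± 0.15 (SE), Ppbp at 1.21 ± 0.48 and Nrgn at 0.84 ± 0.37. The median is the value of Plek, which like Itgb3 (0.91) and Selp (1.22) is expressed by other liver cells too. Erythroid precursors in the liver also cannot be told apart, with a median of 0.028 over 8 of 16 markers. An effect of the treatment on red cells stays an untested biological explanation.

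Acute phase transcripts were higher in antiCD47. A single ill animal is argued against, because the lowest antiCD47 library scored 1.14 and the highest IgG library 0.89. The gap between these libraries is small beside the spread within antiCD47, whose highest score was 2.25. Time of day of collection cannot be told apart: 8 of 14 clock genes with a known phase passed the threshold, all in the direction of a shifted phase, and the labels used here give no collection time. Inflammation under treatment stays open as an untested biological explanation.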

How the results depend on the processing

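Against 1678 genes (842 higher, 836 lower), the total stayed within 1.5 times under DESeq2 size factors, upper quartile scaling, both filters, limma voom and the robust fit (1603 to 1835). It was 3581 with library totals only (428 higher, 3153 lower), 3145 by DESeq2 (1693 and 1452), 4331 by voom with quality weights (2133 and 2198), 3574 at an adjusted p of 0.1 (1850 and 1724) and 502 with a 2-fold minimum (178 and 324). Without IgG 2 and antiCD47 2, chosen after seeing the data, it was 1090 (574 and 516). Leaving out 1 library gave 2 (IgG 4) to 3630 (antiCD47 1) genes, 2 to 1843 higher and 0 to 1787 lower; with 2 genes left, 1386 passed an adjusted p of 0.1. In each such fit all 1678 genes kept direction and an unadjusted p under 0.05. The median ratio of log2 folds was 0.882 to 1.12. Calls ended at the threshold on adjusted p, not through a change of direction. The genes were chosen with all libraries and each fit reuses most of them, so the kept direction was nearly fixed in advance. With the replicate number as a block 2425 genes passed (1214 and 1211). Same-numbered libraries deviated together with r of 0.032, 0.157, -0.023 and 0.035, which shows little sign of pairing by number. For antiCD47 2 the closest IgG library was IgG 2. With 4 libraries per treatment a pairing cannot be ruled out. The authors' deposited table held 4676 genes at an unadjusted p under 0.05. Of 115 genes followed across settings, 104 passed; 2 of these (Hacl1 and Cobl) passed in every one of 19 alternatives, 35 were lost in at least 5, and none turned. Of the 11 that did not pass, 7 passed in at least 1 alternative: Icam1, Ighm, Lpl and Mcm2 in 5 each, Mlkl in 3, Ripk3 in 2 and Acta2 in 1. Lists past by camera were lost with an estimated correlation (adjusted p 0.308 for matrix, Kupffer and heme and iron, 0.477 for necroptosis, 0.607 for inflammatory genes), by fry for necroptosis (0.0763), inflammatory genes (0.219), interferon (0.231), stress response (0.133), hepatocyte identity (0.102), cell cycle (0.0789), drug metabolism and sex-biased genes (0.0763 each), and without both number 2 libraries for inflammatory (0.0647) and sex-biased genes (0.05). Drug metabolism was also lost without IgG 4 (0.0615), and sex-biased genes without IgG 2 (0.0678), without antiCD47 1 (0.136) and with quality weights (0.144). Of the lists not past, cholesterol synthesis passed in 8 of 21 alternatives, bile acids, fatty acid synthesis and gluconeogenesis in 4 each, fatty acid oxidation in 2, and efferocytosis, MHC class II, T and NK cells and oxidative phosphorylation in 1 each. Lists and genes that were not past turned direction as follows, by camera adjusted p for lists and log2 fold change for genes. With library totals only: recruited macrophages 0.979, phagolysosome 0.593, T and NK cells 0.533, immediate early genes 0.64, Cd47 -0.049, Mertk -0.143. That scaling moved the median of all genes to -0.19, which can turn the fold changes of single genes just above 0. Recruited macrophages, T and NK cells and immediate early genes turned from lower to higher by camera, which compares a list with all other genes. Their own medians went lower under that scaling, to -0.249, -0.554 and -0.185, so these genes did not become higher in antiCD47. With upper quartile scaling: phagolysosome 0.918, Mertk -0.021. With no filter: pancreas 0.841. With quality weights: immediate early genes 0.74, Mertk -0.003. Without both number 2 libraries: oxidative phosphorylation 0.797, immediate early genes 0.745, Mertk -0.022. Sirpa was 0.004 with DESeq2 size factors, 0.007 by DESeq2, 0.011 by voom and 0.012 with the block. Without IgG 1: phagolysosome 0.933, immediate early genes 0.965. Without IgG 2: immediate early genes 0.799, Mertk -0.004. Without IgG 3: recruited macrophages 0.507, Sirpa 0.097. Without IgG 4: phagolysosome 0.915, endothelium 0.947, T and NK cells 0.588, Sirpa 0.050. Without antiCD47 1: immediate early genes 0.625, Sirpa 0.009. Without antiCD47 2 or 3: Sirpa 0.026 and 0.038. Without antiCD47 4: oxidative phosphorylation and p53 targets 0.837 each, Mertk -0.041, Timp1 -0.061. Over all 8 such fits, turned or not, values ran from 0.323 to 0.902 for recruited macrophages, 0.458 to 0.936 for phagolysosome, 0.151 to 0.87 for oxidative phosphorylation, 0.516 to 0.915 for p53 targets, 0.113 to 0.947 for endothelium, 0.0363 (without IgG 3) to 0.886 for T and NK cells, 0.449 to 0.965 for immediate early genes, -0.113 to 0.097 for Sirpa, -0.041 to 0.125 for Mertk and -0.061 to 0.568 for Timp1. By camera direction, efferocytosis did not turn in any of its 21 alternatives, and leaving out 1 library gave 0.0445 (without IgG 3) to 0.503. Its median log2 fold change did change sign, from 0.108 to -0.081 with library totals only. The cause was not tested for changes with scaling, tool, weights or single libraries.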

Other observations

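The lists of nucleolar, ribosomal protein, mitochondrially encoded, motile cilia and zonation genes, and the test of biliary cells, were chosen after results had been seen; the test of ribosomal proteins was set before its result was.

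Genes of ribosome assembly in the nucleolus were higher in antiCD47: 29 of 47 passed the edgeR threshold and none was lower. Nop58 (log2 0.97), Rrp12 (0.92), Tsr1 (0.88), Gnl3 (0.84) and Heatr1 (0.80) were among them, and the list median was 0.41. It was 0.22 under scaling by library totals. The list was written after some of its members were seen among the leading genes, so its p-values (7.59e-23 by camera, 0.0512 with an estimated correlation) are not independent evidence. Mitochondrially encoded mRNAs were higher in 11 of 13 cases, with a median of 0.47 (0.29 under scaling by library totals), among them mt-Nd6 (1.05), mt-Nd4l (0.55) and mt-Nd4 (0.52), whereas none of 28 nuclear genes of oxidative phosphorylation passed.

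Motile cilia genes were lower: 7 of 11 measured members passed the threshold, among them Enkur (-2.95), Iqub (-2.69), Capsl (-2.29) and Foxj1 (-1.79). Foxj1, the master regulator of motile cilia, went from 6.53 ± 1.77 to 1.88 ± 1.22 CPM. The largest fold changes lay near the floor and rest on few counts. Enkur went from 0.615 to 0.077 CPM, Iqub from 0.247 to 0.036 and Capsl from 0.86 to 0.172. Pericentral hepatocyte genes, which mark the zone around the central vein, had a median of 0.30 (0.12 under scaling by library totals), with 3 of 15 past the threshold: Cyp2c29, Tbx3 (1.12) and Rnase4 (0.78), all higher. Periportal genes had a median of -0.14 (-0.32 under that scaling), with 3 of 15 past it: Hal and Cdh1 (-1.07) lower and Ctsc (0.84) higher. Ctsc is a member of the phagolysosome list too. Egfr rose by 1.88 ± 0.27 on the log2 scale, from 129 ± 32.9 to 475 ± 162 CPM, and Prg4 by 1.85 ± 0.29. Both were picked after their values were seen.

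A general rise of ribosome related transcripts is argued against as the source of the nucleolar rise: cytosolic ribosomal protein genes had a median of 0.04 (bootstrap interval 0.029 to 0.06), far below the nucleolar median. The test was worded loosely, since it also named any median above 0 as a sign of a general rise, and that was met; the median became -0.149 under scaling by library totals. Fewer biliary cells could also lower motile cilia genes. Their median of -1.66 (-2.29 to -0.41) spans the biliary median of -1.16, but 11 of 30 members were measured, so the relation cannot be told apart from a separate change.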
